A study of Arabidopsis thaliana with 16 samples.

How the data were processed

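Transcript levels were measured in roots of 14-d-old Arabidopsis thaliana seedlings on 16 one-colour Affymetrix arrays with biotin-labelled cRNA. The groups, taken from the sample titles, which name the line HRE1-RNAi20, were wild type normoxia, wild type hypoxia, HRE1-RNAi normoxia and HRE1-RNAi hypoxia, with 4 arrays each. Most descriptions of the HRE1-RNAi samples name RNAi21 to RNAi24 instead, and this conflict was not resolved. Seedlings were kept in the dark during 6 h of treatment, at 3% oxygen for hypoxia. The deposited values are an intensity on a linear scale, 1 per probe set and array. Per the submitters' processing notes they come from MAS5, with no version given. The values lay between 0 and 41828, and in each array the mean without the lowest and highest 2% of probe sets was close to 500, so the arrays had been scaled to a common level. The number of arrays limits the precision.

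The file held 22810 probe sets, of which 64 controls were left out of the gene tests and 22746 were tested. Genes were taken from the table supplied with the series' probes, which pairs 13513 probe sets with 1 gene, 503 with several and 8730 with none. Of the first, 13436 matched the reference gene table by gene identifier and took its symbol, and 77 kept the name in the probe table, giving 13355 distinct genes. Probe sets with several genes or none are named by their identifier. No probe set was paired with HRE1 by either table, so the alternatives planned for its fold change were not run.

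Values were transformed to log2 after adding a pseudocount of 16, which understates the changes of dim probe sets. With limma 3.58.1 in R 4.3.3 a mean per group was fitted over all 16 arrays, with moderated variances (trend and robust) and 12 residual degrees of freedom. The 5 contrasts were hypoxia against normoxia in each line, HRE1-RNAi against wild type in each condition, and the difference of the 2 hypoxia responses. P-values were adjusted by the Benjamini-Hochberg method within each contrast over all 22746 probe sets. Tests were two-sided, and a probe set was called at an adjusted p below 0.05. Named in the text are, for the hypoxia contrasts, up to 12 of the largest called rises and falls. These were taken among probe sets with 1 gene in which no array of 1 group overlapped the other group. Up to 4 members per shifted list and every call of the line contrasts are named too. Each gene was represented in lists by its probe set with the highest mean log2 value.

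In all, 23 gene lists were written down, and the contrasts, named-gene rule and alternatives were chosen, before the data were examined. The 10 lists with at least 3 measured members were tested in all 5 contrasts with camera at a preset correlation of 0.01, adjusted over the 50 pairs of list and contrast. The other 13 had fewer members and are given as single values. A second run estimated the correlation within each list. For a list's members, counts are given over all probe sets and adjusted over the list alone. Families sharing a symbol prefix, 21 with at least 10 measured members, were added after the data were seen, in 105 tests.

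Control probe sets served as array measures: the 25S rRNA signal, the mean difference between 3' and 5' probe sets over 6 pairs (2 each for actin, GAPDH and ubiquitin), the hybridisation controls and the poly-A spikes. Group differences of 10 array measures were tested by exact permutation in 4 contrasts, 40 tests, where 4 against 4 arrays allow 70 arrangements and a smallest p of 0.029. The relation of the line difference to the hypoxia response shares the wild type hypoxia arrays. It was therefore recomputed with these arrays split into 2 pairs and in 20 simulations with HRE1-RNAi hypoxia set to the wild type mean.

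The fit was tested on simulated data with 200 changed probe sets of mixed sizes among 22746. For hypoxia against normoxia in wild type, 18% of those changed by 0.5 log2 were recovered, 50% of those changed by 1 and 94% of those changed by 2. The data gave 4040 calls there, and the adjusted cutoff loosens as more probe sets change. These shares are therefore likely too low for the hypoxia contrasts. For HRE1-RNAi against wild type in hypoxia the shares were 10%, 50% and 92%, and 79.2% at 1 among probe sets above the median brightness. For the difference of responses they were 0%, 26% and 74%.

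Alternatives were pseudocounts of 1 and 64, quantile normalization, centring each array on its median, leaving out the dimmest 40% of probe sets, the replicate number as a fixed or random block, only the 2 groups compared, moderation with neither trend nor robust fit, array weights, and leaving out each array. Stricter counts used an adjusted p below 0.01 or at least a 2-fold change. After the data were seen, both HRE1-RNAi arrays numbered 4 were left out as a further alternative. For lists the alternatives were the estimated correlation, quantile normalization, the filter on dim probe sets and the fixed block, with centring on the median and leaving out both HRE1-RNAi arrays numbered 4 added after the data were seen. Figures were drawn from the result tables with matplotlib. Detection calls and probe-level data were not analysed here.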

Results

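Transcript levels were measured on 16 Affymetrix arrays hybridised with RNA from seedling roots of Arabidopsis thaliana. Wild type (Columbia) was compared with a line in which RNA interference targets HRE1, also named AtERF73, an ethylene response factor gene. Each line was sampled under normoxia and after 6 h at 3% oxygen, giving 4 groups of 4 arrays. The labels call the arrays of a group biological replicates, so the p-values measure the spread between these. The titles name the line HRE1-RNAi20, called HRE1-RNAi here, while most of its sample descriptions name RNAi21 to RNAi24. Whether its arrays come from 1 line or several was therefore left open. Each array held 22746 probe sets besides the manufacturer's controls. The median intensity was 187 in wild type normoxia, 174 in wild type hypoxia, 190.2 in HRE1-RNAi normoxia and 175 in HRE1-RNAi hypoxia. The number of arrays limits the precision. Changes are log2 differences between group means after adding a pseudocount of 16, which understates changes from or to low intensities. They are given with their standard error, and n = 4 arrays per group throughout. A probe set was called at an adjusted p below 0.05, and all tests were two-sided.

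The comparison of hypoxia with normoxia in wild type asks which root transcripts respond to low oxygen. AT5G10040 rose from a mean intensity of 116 to 11388, by 6.53 ± 0.51 log2. CML38, which encodes a calmodulin-like protein, rose from 142 to 6143, by 5.26 ± 0.23. AT5G48430 rose by 6.05 ± 0.19 and AT3G29970 by 5.37 ± 0.34. AT4G30380 rose to 902 from 5.98, below the pseudocount, so the size of its change depends on this (5.25 ± 0.33, 7.09 with a pseudocount of 1 and 3.65 with 64). Further large rises were those of AT4G24110 (5.14 ± 0.24), AT4G33560 (5.05 ± 0.31) and AT2G17850 (4.96 ± 0.26). AT2G47560 rose by 4.34 ± 0.43, AT3G03670 by 4.27 ± 0.35, AT2G43140 by 4.17 ± 0.33 and AT1G36640 by 4.17 ± 0.33. AT3G03670 too lay below the pseudocount in normoxia, at 13.5. On this scale AT1G14960 had the largest fall of the genes named by this rule, from 5938 to 284, a change of -4.33 ± 0.21. AT2G34610 fell from 388 to 5.80, below the pseudocount, so its size and rank depend on this (-4.19 ± 0.23, -5.89 with a pseudocount of 1 and -2.67 with 64). AT4G11210 changed by -3.71 ± 0.27, AT1G23160 by -3.29 ± 0.29 and AT1G72140 by -3.22 ± 0.18. The peroxidase gene AT1G34510 changed by -3.13 ± 0.26. AT4G11190, AT5G38020, AT2G25150, AT3G45680, AT3G57020 and AT2G40460 followed, between -3.20 and -2.95.

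In all, 1637 probe sets were higher and 2403 lower in wild type hypoxia, 17.76% of those tested. At least a 2-fold change was reached by 814 higher and 820 lower ones. The balance between rises and falls depended on the scaling of the arrays. Of the called probe sets, 40.5% were higher on the deposited scale and 53.9% when each array was centred on its median. Without the 2 HRE1-RNAi arrays numbered 4, described at the end, 2008 were higher and 2935 lower. These arrays are not part of this comparison, so its log2 changes stayed the same. Only the spread, estimated over all groups together, changed.

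Of the hypoxia core list, genes known to respond to low oxygen in many tissues, 25 members were measured. In wild type 22 rose, 1 fell and 2 were not called, with a median change of 3.13 (camera adjusted p = 2.0e-42). The shift held with adjusted p = 0.0032 with an estimated correlation. Its risers included AT5G66985 (3.44 ± 0.13), AT5G44730 (3.36 ± 0.15) and AT3G27220 (3.13 ± 0.14). PDC2, a pyruvate decarboxylase gene of ethanolic fermentation, rose by 2.19 ± 0.24, from 889 to 4118. AT5G04120 was the member that fell, by 2.21 on the log2 scale. AT3G10020 (0.16 ± 0.14) and AT5G45960, which was dim with means of 14.75 and 21.25 (0.27 ± 0.37), were not called. The values under AT5G04120 and AT3G10020, here and below, rest on the probe table's pairing, which could not be checked and is in doubt. Adjusted over the list alone, the counts were again 22 and 1.

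**Figure D1:**
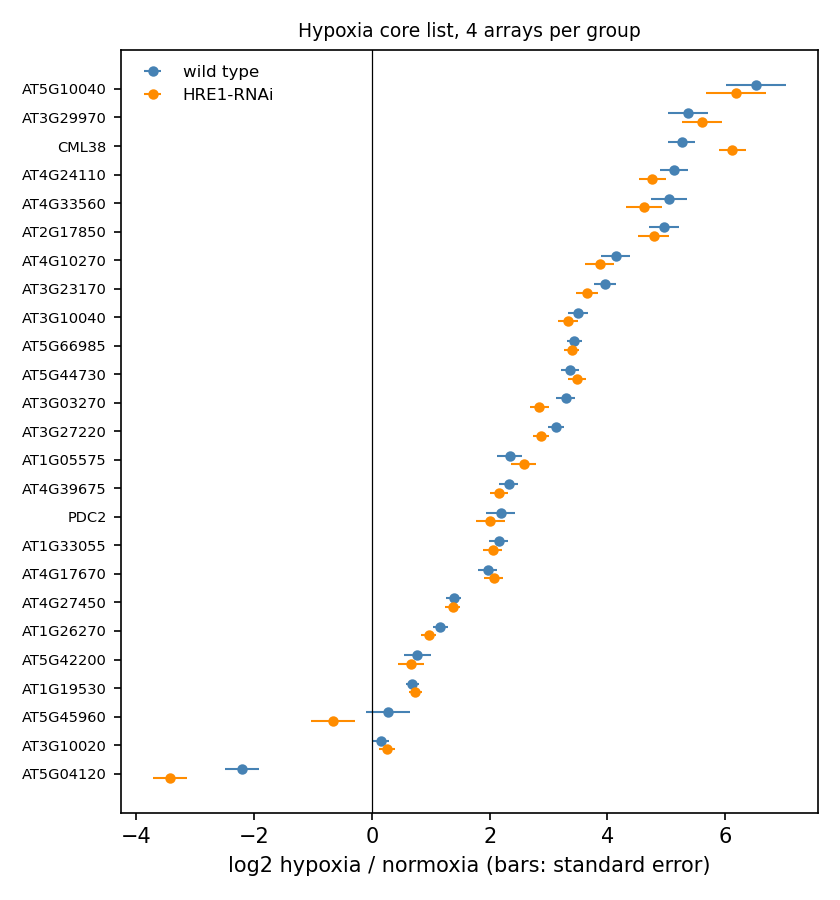
Log2 change from normoxia to hypoxia (horizontal axis) of the 25 measured hypoxia core genes, with points for the means of 4 arrays per group and bars for the standard error. In both lines 22 of the 25 rose, up to 6.53 for AT5G10040 in wild type, and the probe set paired with AT5G04120, a pairing in doubt, fell.

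Heat shock genes and defence-linked transcription factors rose as well. All 6 measured heat shock genes were higher in wild type hypoxia, with a median of 2.24. AT5G51440 rose by 2.38 ± 0.16 and AT2G29500 by 2.35 ± 0.27. The list's camera adjusted p was 7.9e-09, with adjusted p = 0.078 with an estimated correlation. All 4 measured defence and calcium-linked transcription factors rose: STZ by 2.66 ± 0.26, WRKY22 by 2.60 ± 0.22, WRKY53 by 0.99 ± 0.27 and WRKY6 by 0.66 ± 0.16. Their adjusted p was 7.0e-06, with adjusted p = 0.032 with an estimated correlation. WRKY53 had an adjusted p of 0.052 without wild type normoxia array 4.

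The 3 measured root hair genes all fell in wild type hypoxia, with a median of -1.42. XTH26 changed by -2.68 ± 0.32, EXPA7 by -1.42 ± 0.24 and EXPA18 by -1.35 ± 0.22. The list's adjusted p was 0.00044, with adjusted p = 0.19 with an estimated correlation. Of 51 measured class III peroxidases, 13 rose and 13 fell, and 25 were not called. Adjusted over the list alone, 13 rose and 15 fell. AT1G14550 rose by 3.15 ± 0.43 and Prx37 by 2.32 ± 0.20, while AT3G49960 changed by -2.35 ± 0.34 and AT5G15180 by -2.13 ± 0.18. As a set they did not shift (adjusted p = 0.91), and their median of -0.15 and mean of 0.02 differed in sign.

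Of 32 listed glycolysis genes 7 were measured, and these moved little. GAPC2, a glyceraldehyde-3-phosphate dehydrogenase gene, rose by 0.58 ± 0.11 and was the only one called of 7 measured. A second, AT5G63680 at 0.46 ± 0.17, passed when adjusted over the list alone. The list's adjusted p was 0.12. Of 3 ethylene genes RTE1 fell, with a change of -0.74 ± 0.14 (list adjusted p = 0.66). AT3G13610, measured in the iron list of 3, rose by 2.29 ± 0.14 (list adjusted p = 0.13). LHCB4.1 changed by -0.98 ± 0.13 among 3 shoot markers (list adjusted p = 0.090). Of 23 cytochrome P450 genes 3 rose and 4 fell (list adjusted p = 0.94). CYP71B29 rose by 1.65 ± 0.22 and CYP71B28 changed by -1.44 ± 0.19. Signs also differed between the median (0.04) and the mean (-0.19) of the ethylene list.

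Lists with 1 or 2 measured members give single values. The lactate dehydrogenase gene AT4G17260 rose by 2.69 ± 0.12, from 528 to 3496. AT2G21640, of the reactive oxygen list, rose by 1.05 ± 0.29. COR47, a dehydration response gene, changed by -0.89 ± 0.14, while COR15A was not called (0.21 ± 0.31). AUR1, a mitotic kinase gene, changed by -0.52 ± 0.15, and the replication gene PRL by -0.39 ± 0.17, which was not called. MCCA of the sugar starvation list (0.49 ± 0.20), GI of the circadian clock (-0.12 ± 0.15), and DFR (0.75 ± 0.43) and UGT78D2 (0.01 ± 0.21) of flavonoid synthesis were not called. Group VII ERF factors, nitrate genes, aquaporins, jasmonate genes, suberin markers and vascular markers had 0 members among the genes paired with a probe set.

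The same comparison in HRE1-RNAi asks how roots with HRE1 targeted respond to hypoxia. AT5G48430 rose by 6.50 ± 0.19, AT5G10040 by 6.19 ± 0.51 and CML38 by 6.12 ± 0.23. AT1G26380 rose by 5.65 ± 0.36, AT3G29970 by 5.61 ± 0.34 and AT3G03670 by 5.57 ± 0.35. AT2G23270 (5.39 ± 0.36), AT5G22555 (5.24 ± 0.25), AT1G36640 (5.09 ± 0.33) and AT5G39580 (4.90 ± 0.19) were next. The largest falls on this scale among the genes named were those of AT1G14960 (-4.26 ± 0.21), AT2G34610 (-4.12 ± 0.23), AT1G23160 (-3.998 ± 0.29) and CYP718 (-3.65 ± 0.27). AT2G25150, AT5G04120, AT4G11210, AT1G70880 and AT1G49450 changed by -3.58 to -3.32. AT4G25250 changed by -2.97 ± 0.34. Mean intensities lay below the pseudocount for AT3G03670 in normoxia and for AT2G34610, AT1G23160 and AT1G49450 in hypoxia, so the size and rank of these changes depend on it.

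In all, 1708 probe sets were higher and 2427 lower in HRE1-RNAi hypoxia, of which 878 and 859 changed at least 2-fold. Again the share of called probe sets that were higher moved, to 55.6%, when each array was centred on its median. Without the 2 arrays numbered 4 the counts were 1742 and 2472.

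Of the hypoxia core list 22 rose in HRE1-RNAi, 1 fell and 2 were not called, with a median of 2.85 (adjusted p = 5.2e-39, and adjusted p = 0.0032 with an estimated correlation). PDC2 rose by 2.01 ± 0.24 and AT4G17260 by 2.63 ± 0.12. All 6 heat shock genes rose, with a median of 1.70 (adjusted p = 4.0e-07, and adjusted p = 0.13 with an estimated correlation). All 4 defence-linked factors rose, STZ by 3.65 ± 0.26 (adjusted p = 1.7e-06, and adjusted p = 0.028 with an estimated correlation). WRKY6, at 0.50 ± 0.16, was not called with the 2 groups alone (adjusted p = 0.065) or with neither trend nor robust moderation (adjusted p = 0.0502). It was no longer called when any of HRE1-RNAi hypoxia arrays 1 and 2 or HRE1-RNAi normoxia arrays 1, 2 and 3 was left out, with adjusted p values from 0.053 to 0.12. The 3 root hair genes fell, with a median of -1.74 (adjusted p = 0.0028, and adjusted p = 0.23 with an estimated correlation). Of the peroxidases 14 rose and 10 fell, or 17 and 12 adjusted over the list alone, without a shift of the set (adjusted p = 0.13). GAPC2 rose by 0.65 ± 0.11, and the glycolysis list shifted with a median of 0.35 (adjusted p = 0.039, and adjusted p = 0.47 with an estimated correlation). That call was also lost with quantile normalization (adjusted p = 0.054), without the dimmest 40% of probe sets (adjusted p = 0.070) and with each array centred on its median, a setting added for lists after the data were seen (adjusted p = 0.060). AT3G13610 rose by 2.91 ± 0.14 in an iron list whose median was -0.03 and mean 0.74.

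The 2 lines shared most of their response. Of the called probe sets, 1276 were higher and 1736 lower in both lines, where independent lists would share 123 and 256. A further 4 were called in opposite directions, 1024 were called in wild type alone and 1119 in HRE1-RNAi alone. Only 2 of those called in 1 line also had a called difference between the responses. Of the 4040 called in wild type, 98.5% changed in the same direction in HRE1-RNAi. The log2 changes correlated across the 5159 probe sets called in either line (r = 0.94), which are not independent replicates. The 2 comparisons share no arrays.

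**Figure D2:**
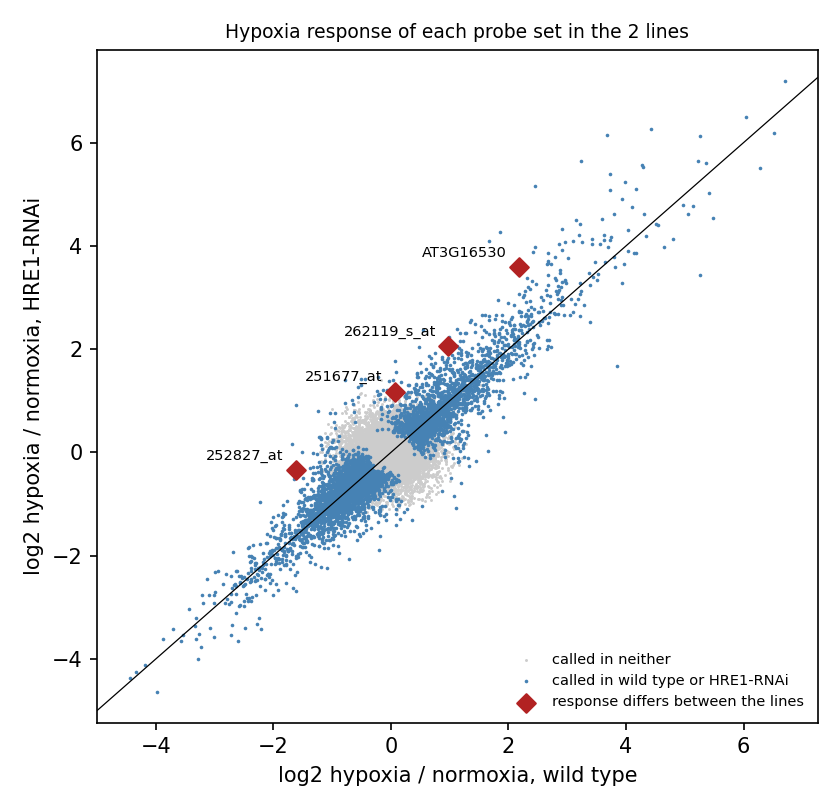
Log2 change from normoxia to hypoxia of each of 22746 probe sets in wild type (horizontal axis) and HRE1-RNAi (vertical axis), as differences of means of 4 arrays, with the line of equal change. The 4 marked probe sets, such as AT3G16530 at 2.19 and 3.58, are those whose response differed between the lines.

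HRE1-RNAi against wild type in normoxia asks what targeting HRE1 changes without low oxygen. The level of HRE1 itself was not analysed here, since no probe set was paired with this gene. A probe set without a gene in the probe table could measure it. Probe set 263494_at was lower in HRE1-RNAi, with a mean of 179 ± 67.1 (SD) against 2620 ± 609, a change of -3.78 ± 0.22 or 13.7-fold (adjusted p = 6.9e-10). AT4G12500 was lower, at 122 against 379 (-1.50 ± 0.22, adjusted p = 0.0027), and AT4G22212 at 10162 against 16253 (-0.67 ± 0.10, adjusted p = 0.0027). Probe sets 251677_at (-1.003 ± 0.13) and 262119_s_at (-0.98 ± 0.10) were also lower. AT5G15360 was higher, at 454 against 178 (1.29 ± 0.17, adjusted p = 0.00062).

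These 6 were all the calls in normoxia, 1 higher and 5 lower. At an unadjusted p below 0.05 limma gave 987 probe sets, where chance gives 1137. Without wild type normoxia array 2 the higher calls were 2, and without HRE1-RNAi normoxia array 4 they were 3. With both arrays numbered 4 left out there were 5 higher and 12 lower, which include the 6. With the 2 groups alone AT4G12500 and AT4G22212 lost their calls (adjusted p = 0.060 for both), and AT4G22212 also with neither trend nor robust moderation (adjusted p = 0.060). Of the 11373 brighter probe sets, 98.3% had a 95% interval that lay within a 2-fold change.

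None of the 10 tested lists had a called member in normoxia, and adjusted over the list alone the probe set paired with AT5G04120 (1.09 ± 0.29) was higher and CML38 (-0.97 ± 0.23) and AT3G13610 (-0.45 ± 0.14) lower. By camera the hypoxia core list (median 0.07, adjusted p = 0.037, and adjusted p = 0.53 with an estimated correlation) lay above the other genes. So did the heat shock list (median 0.26, adjusted p = 0.045, and adjusted p = 0.47 with an estimated correlation). Without the dimmest 40% neither was called (adjusted p = 0.17 and adjusted p = 0.069), nor was the hypoxia core list with quantile normalization (adjusted p = 0.054). Without the arrays numbered 4 neither list was called (adjusted p = 0.38 and adjusted p = 0.66), and both medians were below 0, at -0.02 and -0.01. With all arrays, median and mean differed in sign for peroxidases (0.03 and -0.06) and cytochrome P450 genes (0.05 and -0.07), neither of which shifted.

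HRE1-RNAi against wild type in hypoxia asks what targeting HRE1 changes under low oxygen, where the hypoxia response has been induced. Probe set 263494_at was again lower, at 133 ± 39.98 (SD) against 1846 ± 236, a change of -3.67 ± 0.22 or 12.7-fold (adjusted p = 1.3e-09). Probe set 249490_s_at, which matches several genes, was higher at 404 against 141 (1.40 ± 0.19, adjusted p = 0.0020). AT5G15360 was higher at 350.05 against 152 (1.11 ± 0.17, adjusted p = 0.0081). Probe set 252827_at was higher (0.81 ± 0.13, adjusted p = 0.029), and 256081_at was lower at 403 against 734 (-0.83 ± 0.14, adjusted p = 0.030).

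These were all the calls in hypoxia, 3 higher and 2 lower. At an unadjusted p below 0.05 limma gave 1036 probe sets, again fewer than the 1137 of chance. Of the 11373 brighter probe sets, 97.9% had a 95% interval within a 2-fold change. Probe set 256081_at lost its call without any 1 of 10 arrays. These were HRE1-RNAi hypoxia 1 to 4, wild type hypoxia 1, 3 and 4, HRE1-RNAi normoxia 1 and wild type normoxia 2 and 3, with adjusted p values from 0.051 to 0.25. Probe set 252827_at lost it without HRE1-RNAi hypoxia 2, 3 or 4, wild type hypoxia 1, 2, 3 or 4 or wild type normoxia 2 or 3 (0.051 to 0.15). AT5G15360 lost it without HRE1-RNAi hypoxia 3 or wild type hypoxia 1 or 4 (0.068 to 0.072). With the 2 groups alone AT5G15360 (adjusted p = 0.11), 252827_at (adjusted p = 0.26) and 256081_at (adjusted p = 0.25) lost their calls. With neither trend nor robust moderation 252827_at (adjusted p = 0.16) and 256081_at (adjusted p = 0.079) lost theirs.

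The hypoxia core list had 0 called members of 25 between the lines in hypoxia, with a median of -0.07 (adjusted p = 0.85). PDC2 differed by -0.10 ± 0.24, AT4G17260 by -0.06 ± 0.12 and AT5G66985 by -0.06 ± 0.13. Peroxidases had 0 called of 51, and 3 were higher adjusted over the list alone: AT1G34510 (1.04 ± 0.26), AT5G64110 (1.02 ± 0.28) and AT5G06730 (0.66 ± 0.20). Together 38 of the 51 lay above 0, with a median of 0.17 (camera adjusted p = 1.7e-06, and adjusted p = 0.19 with an estimated correlation). Of the 3 root hair genes 0 were called, and XTH26 (0.88 ± 0.32) and EXPA18 (0.69 ± 0.22) were higher adjusted over the list alone (list adjusted p = 0.0046, and adjusted p = 0.23 with an estimated correlation). Without the arrays numbered 4 the root hair list was not called (adjusted p = 0.056), while its median was 0.72 against 0.69 with them. Of the cytochrome P450 genes CYP71B6 (0.55 ± 0.13) was higher adjusted over the list alone.

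**Figure D3:**
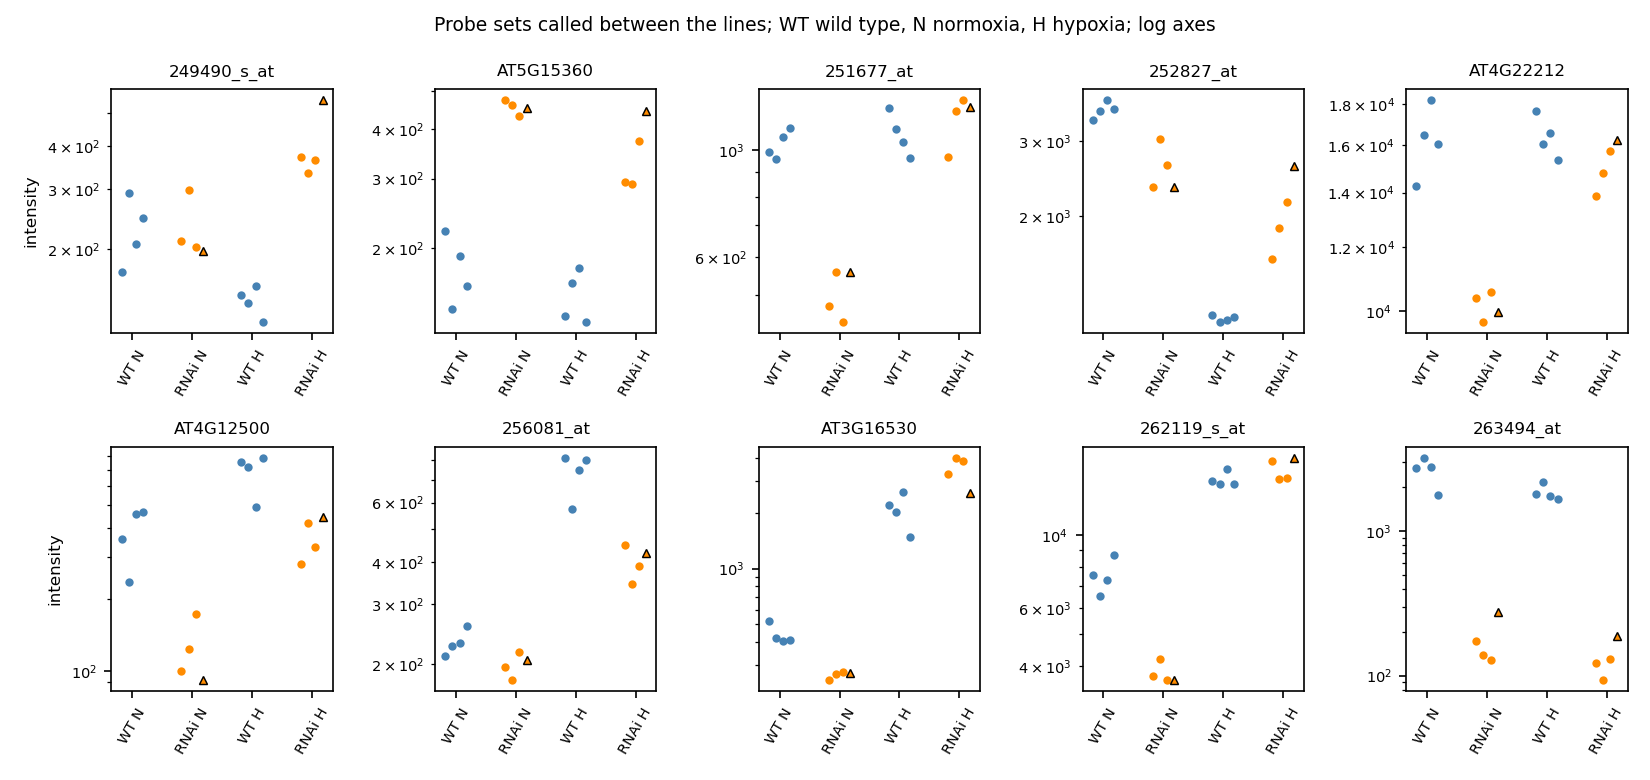
Intensity (vertical log axes) in each of the 16 arrays of the 10 probe sets called between the lines or in the difference of responses, with 1 point per array, orange for HRE1-RNAi, and triangles for its arrays numbered 4. Probe set 263494_at averaged 2620 and 1846 in wild type against 179 and 133 in HRE1-RNAi.

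The difference of the hypoxia response between the lines asks which genes respond differently when HRE1 is targeted. It was called for 4 probe sets, all with a positive difference, HRE1-RNAi minus wild type. With neither trend nor robust moderation only 262119_s_at of these was still called, with adjusted p = 0.11 for AT3G16530, adjusted p = 0.053 for 252827_at and adjusted p = 0.064 for 251677_at. That setting called 5 probe sets in all, of which only 1 was shared with the main fit. AT3G16530 rose by 3.58 ± 0.16 in HRE1-RNAi and by 2.19 ± 0.16 in wild type, a difference of 1.40 ± 0.23 (adjusted p = 0.022). Probe set 262119_s_at rose by 2.06 and 0.98, a difference of 1.09 ± 0.15 (adjusted p = 0.0060). Probe set 251677_at rose by 1.17 in HRE1-RNAi and changed by 0.07 in wild type (1.11 ± 0.18, adjusted p = 0.022). Both 262119_s_at and 251677_at started lower in HRE1-RNAi normoxia and reached wild type levels in hypoxia. Probe set 252827_at fell in wild type by 1.61 on the log2 scale and was not called in HRE1-RNAi at -0.34 (1.27 ± 0.19, adjusted p = 0.013).

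Negative differences were called by limma for 0 probe sets, so the weaker response that was called is the fall of 252827_at. An unadjusted limma p below 0.05 was reached by 770. Of the 11373 brighter probe sets, 91.0% had a 95% interval of the difference within 2-fold. The hypoxia core list lay below 0 in 18 of 25 members and was not called as a shift (median -0.17, adjusted p = 0.090). Peroxidases lay above 0 in 35 of 51, with a median of 0.32 and 0 called (adjusted p = 3.9e-05, and adjusted p = 0.23 with an estimated correlation). Without the arrays numbered 4 their median was 0.19 (adjusted p = 0.00042). Adjusted over the list alone, STZ (0.99 ± 0.36) and AT3G13610 (0.61 ± 0.19) had a positive and AT5G51440 (-0.71 ± 0.23) a negative difference. The 4 calls became 1 without HRE1-RNAi hypoxia 3, HRE1-RNAi normoxia 1 or wild type normoxia 3. They became 2 without HRE1-RNAi hypoxia 2, wild type hypoxia 2 or wild type normoxia 1, 2 or 4. Probe set 262119_s_at held its call in each of these.

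Whether the line difference in hypoxia follows the hypoxia response was examined across the probe sets called in wild type, 4040 with all arrays. The 2 comparisons share the wild type hypoxia arrays, and the log2 values correlated at r = -0.12 with a covariance of -0.04. In 20 simulations with HRE1-RNAi unchanged, the shared arrays alone gave r = -0.25 on average (-0.29 to -0.23) and a covariance of -0.08 (-0.089 to -0.072). The observed values lay above all 20. The simulations drew independent noise for each probe set and called 5601 on average, so they match the data only in part. With the 4 shared arrays split into 2 pairs, 1 per comparison, the 6 splits gave r from -0.09 to 0.29 and a mean covariance of 0.03, across 2587 to 3605 called probe sets. Simulated pairs gave r from -0.04 to 0.03, with 4031 called on average. The splits differed in sign and the simulations lack deviations that span an array, so no common direction was shown. Probe sets are not independent replicates.

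HRE1-RNAi arrays numbered 4 in normoxia and hypoxia departed together from their groups, with a correlation of their deviations of 0.69 across probe sets. Wild type hypoxia array 3 deviated with the 2 as well, at 0.51 and 0.28. The 2 HRE1-RNAi arrays had the highest mean difference between 3' and 5' probe sets over 6 pairs of actin, GAPDH and ubiquitin. It was 1.32 and 1.35 log2 against at most 1.20 in the others. In single pairs this did not hold throughout, as both lay above all others in 1 pair of the 6, 1 of them in 2 and neither in 3. AT3G03670 and AT3G57020 were among the genes in which HRE1-RNAi hypoxia array 4 stood apart from the 3 others. The 25S rRNA control rose from a mean intensity of 2549 in wild type normoxia to 15473 in hypoxia, by 2.89 log2 or 7.43-fold. All 4 arrays per group were apart (exact permutation p = 0.029, the smallest that 4 against 4 can give, and 0.19 adjusted over 40 tests of array measures). In HRE1-RNAi it averaged 1740 and 13010 (exact permutation p = 0.086, adjusted 0.34), with the lowest value of each group in array 4 (273 and 1776). Hybridisation controls were level, at 11.31 and 11.35 log2 in wild type hypoxia and normoxia. The mean of the 3 root hair markers fell with hypoxia, by 1.82 on the log2 scale in wild type, and that of the 2 dividing cell markers by 0.45 (exact permutation p = 0.029, adjusted 0.19).

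**Figure D4:**
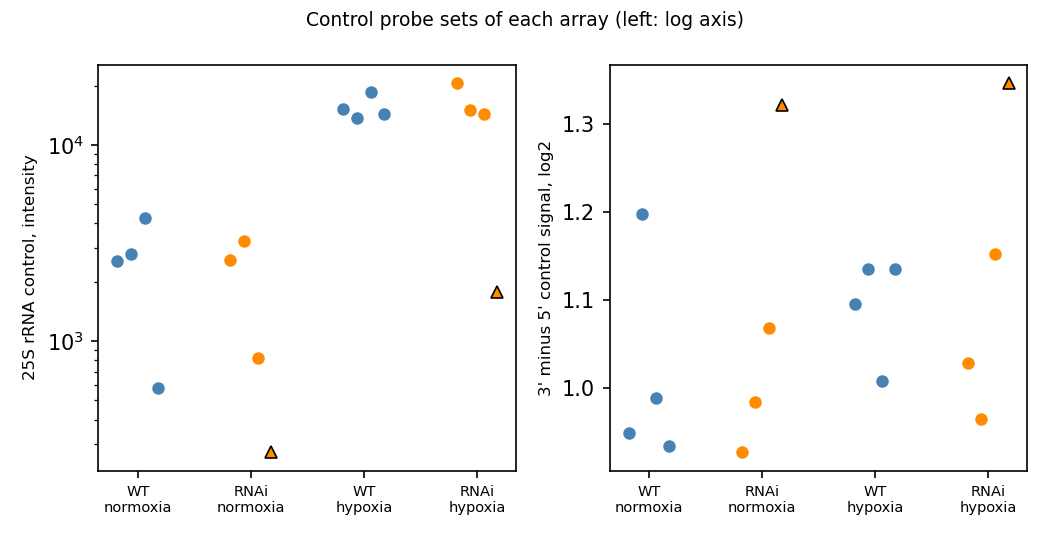
Intensity of the 25S rRNA control (left, log axis) and mean 3' minus 5' log2 signal over the 6 control pairs (right) in each array by group, with triangles for HRE1-RNAi arrays numbered 4. Wild type hypoxia arrays averaged 15473 against 2549 in normoxia, and the triangles had the highest 3' minus 5' values, 1.32 and 1.35.

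Without the 2 arrays numbered 4, a choice made after the data were seen, further probe sets separated the lines. Arrays of only 1 line were left out, which can itself move the line difference. With all arrays these further differences were smaller and not called, such as -1.03 for AT5G22555 in normoxia and 0.82 for GSTU20 in hypoxia. Without the 2 arrays AT5G22555 was lower in normoxia (-1.30 ± 0.19, adjusted p = 0.0018), as were AT2G47950 (-1.01 ± 0.14) and AT2G38870 (-0.68 ± 0.13). SWEET11, a sugar transporter gene, was higher (0.59 ± 0.11, adjusted p = 0.040). In hypoxia 13 were higher and 6 lower, including the 5 called with all arrays. The glutathione transferase gene GSTU20 (0.98 ± 0.18), EXO (0.80 ± 0.15), AT3G16530 (0.84 ± 0.15) and the peroxidase gene AT1G34510 (1.26 ± 0.24) were higher. AT3G47510 was lower (-1.01 ± 0.15). Probe set 260451_at was lower too, at 2122 against 7673 (-1.82 ± 0.20, adjusted p = 4.3e-05). The probe table gives it no gene, so whether it measures the RNAi target itself or another transcript was left open. It rose with hypoxia in wild type by 3.84 ± 0.29 and less in HRE1-RNAi, a difference of -2.04 ± 0.28 (adjusted p = 0.0034). With all arrays that difference was -2.17 ± 0.41 and not called (adjusted p = 0.15). In all, 5 probe sets then had a higher and 1 a lower difference of the response, and the 4 called with all arrays were among them.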

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

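Of the tests below, those on the 3' to 5' signal, on a shared batch, on the 25S control and on probe set 263494_at were chosen only after the result was seen, while the regroupings of arrays and the label test had been written down first.

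Single arrays were marked where, among the 4 of a group, the gap to the nearest other array took most of the range, which chance does in about 1 of 20 groups. Among 40 groups of array measures 4 were marked, where chance gives 2, and among 272 groups of named genes 13, where chance gives 13.6. The array measures were the share of probe sets below an intensity of 50 in HRE1-RNAi hypoxia array 3 (ratio 0.919), the 25S signal in HRE1-RNAi hypoxia array 4 (0.853), and the poly-A spikes (0.841) and shoot markers (0.838) in HRE1-RNAi hypoxia array 1. In HRE1-RNAi hypoxia array 4 the genes were AT3G03670 (0.837), AT1G36640 (0.876), AT3G57020 (0.879), AT5G08570 (0.860) and AT5G06730 (0.841). In HRE1-RNAi normoxia array 4 they were AT3G57020 (0.872) and AT4G25250 (0.890). In wild type normoxia they were AT2G47560 (0.867) and AT3G16530 (0.830) in array 1, AT1G14960 (0.841) in array 2 and AT3G03670 (0.862) in array 4. The others were AT5G44730 (0.878) in wild type hypoxia array 3 and 249490_s_at (0.846) in HRE1-RNAi normoxia array 2. The 2 HRE1-RNAi arrays numbered 4 gave 7 of the 13.

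A second kind of mark was a response that differed between the lines by a test of the difference itself. It fell on AT3G16530 (1.40), 252827_at (1.27), 251677_at (1.11) and 262119_s_at (1.09), and on the class III peroxidases (median 0.32). The peroxidase list was not called with an estimated correlation (adjusted p = 0.23), and its median was 0.19 without the arrays numbered 4. The last kind of mark was a change in control probe sets that no comparison of genes covers, the 25S signal in wild type (2.89).

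The HRE1-RNAi arrays numbered 4 deviated together. A wrong treatment label on the hypoxia array is argued against by its mean over the hypoxia core genes, which lay 0.0050 log2 from that of the 3 other HRE1-RNAi hypoxia arrays and 2.66 above its normoxia group. A batch shared by all arrays numbered 4 is argued against by the mean correlation of deviations with the wild type arrays of that number, -0.026. This mean joins opposite signs. Wild type normoxia array 4 correlated with the 2 at 0.12 and 0.17, and wild type hypoxia array 4 at -0.29 and -0.11. The 25S signal was also lowest in array 4 in wild type normoxia (577), though not in wild type hypoxia. A batch shared by only part of the arrays numbered 4 was left open. A lower RNA integrity may be a source and remains open. Both HRE1-RNAi arrays numbered 4 lay at least 0.12 log2 above all 14 others in the mean 3' minus 5' signal. In single pairs both did so in only 1 of 6, and neither did in ubiquitin. The deviation was not particular to them, as wild type hypoxia array 3 correlated with the 2 at 0.51 and 0.28. Wild type normoxia array 3 did so at 0.30 and 0.19. The 3' minus 5' signals of these wild type arrays were 1.01 and 0.99, so part of the deviation occurred without a raised signal. That the root samples of the 2 HRE1-RNAi arrays themselves differed was not tested.

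The 25S control was brighter in wild type hypoxia. Brighter hybridisation is argued against by the hybridisation controls, which differed by -0.038 log2. A smaller mRNA share of total RNA is argued against as the whole cause, since 25S remained 2.102 log2 higher relative to the poly-A spikes (exact permutation p = 0.029, the smallest possible with 4 against 4). The spikes themselves differed by 0.79 log2 (exact permutation p = 0.057), so part of the change could still come from that share. A change of rRNA processing or polyadenylation in hypoxia was not tested.

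Probe set 263494_at was lower in HRE1-RNAi in both conditions. The arrays numbered 4 do not carry this, as the change in normoxia was -3.99 log2 without them. An effect that needs hypoxia is argued against by the difference between the 2 conditions, 0.11 log2 with a standard error of 0.31. A consequence of HRE1 targeting and a change specific to this line, such as an insertion or a second target of the RNAi construct, could both give it. The probe table gives this probe set no gene, so a match to the RNAi target itself was considered too. HRE1 is on the hypoxia core list, while this probe set did not rise with hypoxia in wild type (-0.48 ± 0.22, limma adjusted p = 0.15). That argues against such a match. The labels leave open whether the arrays come from 1 line or several. A consequence of HRE1 targeting and a change specific to this line were therefore not parted.

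Other groupings of the same arrays tested whether chance gives as many calls. For hypoxia against normoxia chance is argued against, with 4477 calls in wild type and 3365 in HRE1-RNAi in fits of 8 arrays against at most 0 in other splits. In each of these, 1 of 35 splits, the real one, reached that number. Other splits there mix hypoxia and normoxia arrays on both sides, so the hypoxia response widens their spread and few calls were likely. Chance is also argued against for the lines in normoxia, with 4 calls against at most 0 (1 of 35). The same holds for the difference of responses, with 4 against at most 1 (1 of 100 drawn groupings). These shares, the real grouping alone, are the smallest possible and were not adjusted for the number of tests. Chance cannot be excluded for the number of calls between the lines in hypoxia, where 2 of 35 splits reached the 3 calls and the highest other split had 3.

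The splits between 2 groups used fits of their 8 arrays, while the list calls given earlier come from the fit of all 16. For gene lists chance is argued against only weakly in wild type hypoxia, with 5 lists called against at most 4 in other splits (1 of 35). That share is the smallest possible and was not adjusted for the number of tests. For HRE1-RNAi hypoxia, with 5 lists against up to 6 (6 of 35), the splits do not decide. Many splits of hypoxia and normoxia arrays divide the hypoxia arrays unevenly, so they keep part of the hypoxia response, which can itself call lists. The hypoxia core list in HRE1-RNAi held its shift with an estimated correlation (camera adjusted p = 0.0032). Chance cannot be excluded for the lines in hypoxia, with 2 against up to 3 (14 of 35), nor for the difference of responses, with 1 against up to 5 (66 of 100). Between the lines in normoxia 0 lists were called with 8 arrays, which all 35 of 35 splits must reach (highest other 4), so this decides nothing and the 2 list calls of the fit of all arrays were not tested. A preset correlation of 0.01 does not allow for genes of a list that vary together between arrays. Whether such genes gave the list calls in other splits was not tested.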

How the results depend on the processing

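The alternative without both HRE1-RNAi arrays numbered 4, and for lists the centring of each array on its median, were chosen after the result was seen. The labels do not say that a replicate number marks a shared origin, so the arrays were not paired. As a hint from the data, 10 of 16 correlated best with an array of their own number, though not all, and 12 of 24 pairs of the same number correlated above 0.1 (median 0.108, against -0.0538 for different numbers). With the replicate block fixed the counts were 1779 higher and 2598 lower in wild type hypoxia, 1822 and 2654 in HRE1-RNAi hypoxia, 1 and 5 between the lines in normoxia, 4 and 2 in hypoxia, and 5 and 0 for the difference. With a random block they were 1716 and 2517, 1770 and 2562, 1 and 5, 3 and 2, and 4 and 0. Requiring a 2-fold change left 814 higher and 820 lower in wild type and 878 and 859 in HRE1-RNAi. Between the lines it left 1 and 3 in normoxia, 2 and 1 in hypoxia, and 4 and 0 for the difference. An adjusted p below 0.01 left 1496 and 1519 lower with hypoxia (higher counts are not listed here), 1 lower between the lines in hypoxia and 1 higher for the difference. All 6 calls in normoxia stayed below 0.01, as did the higher calls of 249490_s_at and AT5G15360 in hypoxia. Higher calls in normoxia became 2 with quantile normalization, without the dimmest 40% or with array weights, and 5 without the arrays numbered 4. Lower calls there became 8 with a pseudocount of 1, 3 with the 2 groups alone, 16 with array weights and 12 without those arrays. In hypoxia higher calls became 6 with a pseudocount of 64, 1 with the 2 groups alone, 5 with array weights and 13 without those arrays, and lower calls 1 with neither trend nor robust moderation and 6 without those arrays. Lower calls for the difference became 1 with each array centred on its median, 2 with array weights and 1 without those arrays. Leaving out single arrays gave 1356 to 1801 higher and 1936 to 2624 lower in wild type, and 1467 to 1760 and 1937 to 2593 in HRE1-RNAi. Between the lines it gave 1 to 3 and 5 to 7 in normoxia, 1 to 3 and 1 to 3 in hypoxia, and 1 to 5 and 0 to 1 for the difference. Of 14 list shifts, 4 held with an estimated correlation. Without the dimmest 40% 9 shifts were called, 8 of the 14 and 1 other, while 3 of the 14 were lost and 3 could not be tested. Signs reversed for AT5G48570 in normoxia with array weights (-0.010) and without HRE1-RNAi normoxia array 4, alone or with its hypoxia counterpart (-0.041), with 0.54 as the highest value without 1 array. They reversed for EXPA7 in hypoxia without HRE1-RNAi hypoxia array 3 (-0.12), wild type hypoxia array 1 (-0.09) or HRE1-RNAi hypoxia array 4, alone or with its counterpart (-0.080), with 0.37 as the highest. The alternatives planned for HRE1 itself were not run. The cause of these changes was not tested.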

Other observations

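Gene families by symbol prefix were looked at after the results were seen, and their tests are a description. Serine carboxypeptidase-like genes (SCPL) fell with hypoxia in wild type: of 29 measured, 12 were lower and 1 higher, with a median of -0.51 (adjusted p = 0.010, and adjusted p = 0.72 with an estimated correlation). Members that fell were scpl29 (-1.59 ± 0.15, from 1779 to 588), SCPL27 (-1.20 ± 0.23) and SCPL49 (-0.94 ± 0.18), while SCPL45 rose by 0.79 ± 0.12. The median stayed negative with quantile normalization (-0.45) and with each array centred on its median (-0.42). In HRE1-RNAi 10 were lower and 3 higher, with a median of -0.23 (adjusted p = 0.21, and adjusted p = 0.72 with an estimated correlation).

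Transcripts of the mitochondrial genome were lower in HRE1-RNAi normoxia in all 16 measured genes, with a median of -0.33 and 0 called singly by limma (camera adjusted p = 0.017, and adjusted p = 0.72 with an estimated correlation). Among them nad1 differed by -0.80 ± 0.30 and ccb206 by -0.64 ± 0.27. The median was -0.27 with quantile normalization, -0.35 with each array centred on its median and -0.31 without the arrays numbered 4. In hypoxia 10 of 16 lay below 0, with a median of -0.08. Most of these transcripts were dim, as nad1 averaged 131 in wild type and 64.9 in HRE1-RNAi.

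A candidate explanation for the few calls between the lines is that the arrays numbered 4 widened the spread or moved the HRE1-RNAi means. Each further call between the lines in normoxia or hypoxia also had a larger difference without them. In normoxia this was 1.17 against 0.71 for 260956_at and 0.588 against 0.581 for SWEET11. Arrays of only 1 line were left out, which can itself move the line difference. Without the arrays numbered 4 the calls were 5 higher and 12 lower in normoxia and 13 higher and 6 lower in hypoxia. Probe set 260451_at then differed in its response by -2.04 log2. It may mark a transcript whose induction depends on HRE1, or be the RNAi target itself, as the probe table gives it no gene. The sequence of its probes would part these, and new arrays of this line, or a quantitative PCR of this transcript in a second line, would test the first.

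The probe sets 262119_s_at and 251677_at were lower in HRE1-RNAi normoxia and level with wild type in hypoxia. A role of HRE1 in their basal level could give this, and so could a difference between the seedling batches before treatment. The arrays numbered 4 were not the reason, as the differences of response without them were called at 1.03 for 262119_s_at and 1.13 for 251677_at, beside 5 higher calls in all. A time course in both lines would part the explanations.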
